A study of Mus musculus with 6 samples.

How the data were processed

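C2C12 is an established mouse myoblast line whose cells fuse into contractile myotubes when serum is lowered. Per the labels' protocols, cells were grown to confluence with 20% fetal bovine serum, kept in 2% horse serum over 5 days of differentiation, and then given 500 µM palmitate or 1% bovine serum albumin (BSA) for 16 h. Palmitate is a saturated long-chain fatty acid, and per the series' design text it was bound to fatty acid-free BSA before use. Biotin-labelled cRNA was made from 10 µg of total RNA per the labels, and each sample was hybridised to an Affymetrix mouse 430A 2.0 array per the design text. There were 2 groups of 3 arrays. The labels number the replicates but do not say that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

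The deposited values are signal intensities on a linear scale, 1 per probe set, made with MAS 5 per the submitters' processing notes. The settings of that software were not given in the sources used here. The 2% trimmed mean of the signal was close to 1500 on each of the 6 arrays (between 1500.5 and 1500.56), so the arrays had already been scaled to equal average signal. Such a scaling hides a change of most transcripts in the same direction. Detection calls and scan dates were not used here, so whether a dim probe set lay above background is not known and batches could not be examined.

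The table held 22690 probe sets, of which 64 were controls of the array. Of the other 22626, the platform annotation paired 20380 with 1 gene symbol, 691 with several and 1555 with none, and only probe sets with 1 symbol were named. Symbols were checked against the RefSeq gene table of mouse assembly GRCm38.p6, and 0 were changed. No genome build belongs to the array values, so no coordinates are given. A gene was represented by its probe set with the highest mean log2 signal over the 6 arrays.

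Signals were log2 transformed with no offset. Probe sets above the 40th percentile of mean log2 signal (a signal of 267.1) were kept, which left 13575, of which 12522 had 1 symbol and covered 7931 genes. Palmitate was compared with BSA by limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over the 13575 probe sets and a threshold of 0.05. The fit had 4 residual degrees of freedom per probe set, and the shared variance estimate added 7.98. The median SE of a log2 fold change was 0.22.

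Before the data were examined, 30 gene lists were fixed, covering mitochondrial, lipid, stress, inflammatory and muscle genes and markers of other cell types. The 28 lists with at least 5 measured genes were tested with limma's camera at its preset inter-gene correlation of 0.01, adjusted over the 28 lists. Camera asks whether the genes of a list shift relative to the other genes measured. It was run again with the correlation estimated for each list, and fry was run as well. Fry tests whether the genes of a list move, on balance, in a single direction, and does not compare them with other genes.

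The genes to be named were also set beforehand. They were the 15 largest rises and the 15 largest falls among genes past the threshold whose palmitate arrays all lay on the same side of the BSA arrays, up to 4 members of each list with the smallest p, and 25 further genes wherever measured. Most list members under this rule that did not pass the threshold are left out of the text. Examples are Pprc1 (log2 fold change 0.53, limma adjusted p = 0.0515), Six4 (-0.52, adjusted p = 0.0515) and Csf1r (1.26, adjusted p = 0.0805). Members named outside this rule were chosen after their values were seen, because a count of 5 or fewer covered them. They are Cxcl5, Tlr2, Vcam1, Gpx1, Ern1, Ccn1, Atp5j2, Uqcrh, Sdhd, Eci2, Cat, Lpin3, Pfkl, Psmb10, Psmd11, Psmd14, Casp6, Xiap and Sesn1. Cpt1b was not analysed here. Control probe sets were compared by an exact permutation test, which cannot give a p under 0.1 with 3 arrays against 3.

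The fit was tested on 10 simulated data sets of the palmitate against BSA comparison, each of 13575 probe sets with 200 changed by known folds. It recovered 13.7% of those changed 1.5-fold, 56.7% of those changed 2-fold and 95.2% of those changed 4-fold, and 6.06% of its calls were false. A simulated list shifted by 0.3 was called in 10 of 10 data sets and 0 unshifted lists were called. The simulated genes were independent, so this does not test lists whose genes vary together between arrays. Far more probe sets passed in the data (2609) than were changed in a simulated set (200), which loosens the adjusted threshold. The simulated noise was normal, with variances taken from limma's own shared estimate, so the share of false calls was largely set by that model. The recovery rates and the share of false calls therefore hold for the simulated setting and not for the data.

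The alternatives fixed beforehand were median, 75th percentile and quantile scaling, an offset before the log, no filter and a filter at the 60th percentile, a fit without the intensity trend or with a robust trend, the replicate number as a block, the mean over all probe sets of a gene, and each array left out in turn. A scaling to the hybridisation controls and a fit without both arrays at the far end of principal component 2 were added after the data were seen.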

Results

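The series asked how C2C12 myotubes respond to palmitate, with transcripts measured on 3 arrays of myotubes given palmitate for 16 h and 3 arrays of myotubes given BSA. Arrays of the same group correlated at 0.943 to 0.959 over the 13575 probe sets tested, and arrays of different groups at 0.883 to 0.910. The first principal component held 51.8% of the variance and separated the groups. The second held 17.7%, with BSA replicate 1 and palmitate replicate 2 together at its far end. The log2 ratio of the 3' to the 5' Gapdh control probe set, a measure of RNA integrity, was 0.27 ± 0.07 (SD, n = 3) with BSA and 0.07 ± 0.24 (SD, n = 3) with palmitate (exact permutation p = 0.2, two-sided, where 0.1 is the smallest possible). For b-actin it was 0.53 ± 0.07 and 0.41 ± 0.15 (exact permutation p = 0.5). Palmitate replicate 2 had the lowest ratio for both (-0.20 for Gapdh, against 0.19 and 0.22 on the other palmitate arrays). Without it the group difference went from -0.20 to -0.067 for Gapdh and from -0.12 to -0.033 for b-actin.

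Palmitate-treated myotubes had higher transcripts of the unfolded protein response (24 of 25 genes), of heat shock proteins (14 of 17) and of immediate-early genes (19 of 24) than BSA-treated myotubes, and these were the only lists to pass with an estimated correlation as well. Lists that passed with camera's preset correlation but not with an estimated one included ATF4 targets (24 of 30 higher) and oxidative stress genes (10 of 20 higher). Among the lower ones were those of the extracellular matrix (22 of 28), the cell cycle (22 of 32), the interferon response (12 of 22) and oxidative phosphorylation (14 of 73). The largest rise among named genes was that of Hmox1, which encodes heme oxygenase, from a signal of 680.2 ± 129.6 to 8711 ± 2438 (SD, n = 3), or 12.7-fold (limma adjusted p = 1.68e-06). Plin2, which encodes a coat protein of lipid droplets, rose 4.11-fold. The cytochrome P450 gene Cyp1b1 was 11.6-fold lower with palmitate, at 1305 ± 701.9 against 14131 ± 3605 (SD, n = 3).

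In all, 2609 of 13575 probe sets (19.2%) passed the threshold, 1172 higher and 1437 lower with palmitate, and 420 and 644 of these differed at least 2-fold. Of 7931 genes, each by its representative probe set, 628 rose and 974 fell. The 2 groups did not overlap for 37.2% of probe sets, where chance gives 10%. The split into higher and lower rests on how the arrays are scaled. The 9 hybridisation control probe sets, which measure RNAs added to each sample, had a mean log2 signal of 12.82 ± 0.14 (SD, n = 3) with BSA and 13.15 ± 0.14 with palmitate (exact permutation p = 0.1, the smallest possible). Whether less labelled sample RNA or the scale factor of the MAS 5.0 signals made the controls brighter was not settled, so neither scaling is taken as the right one. Scaling the arrays to these controls, an alternative added after the data were seen, moved the median of all probe sets to -0.34 and gave 404 higher and 3169 lower, so that 11.3% of the calls were higher against 44.9% as deposited. Of the 2609 calls, 1837 passed there in the same direction and 0 changed sign. None could change sign, since this scaling lowers every log2 fold change by 0.33 and the smallest one called was 0.37 from 0. Without BSA replicate 2 the count was 1579, with 746 higher and 833 lower.

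**Figure D1:**
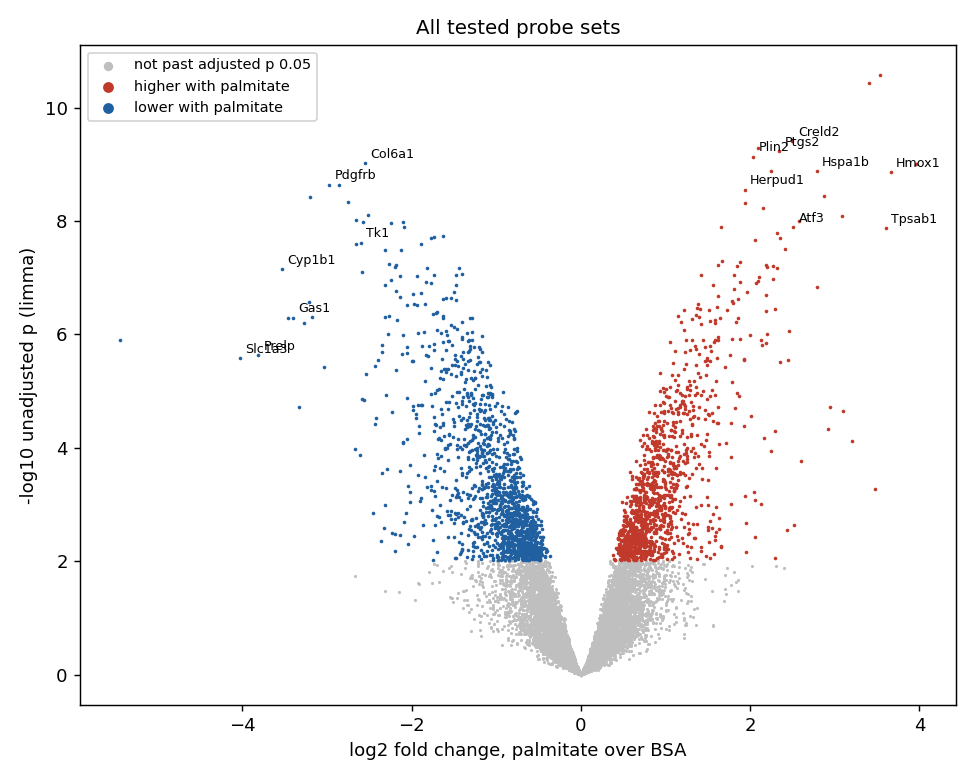
Each point is a probe set, with its log2 fold change (palmitate over BSA) on the horizontal axis and -log10 of its unadjusted limma p on the vertical axis. Red points (1172) were higher and blue points (1437) lower with palmitate at an adjusted p under 0.05, grey points did not pass, and after hybridisation control scaling the split was 404 and 3169.

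From here on, a value beside a gene is its log2 fold change, palmitate over BSA, ± SE from limma, with n = 3 arrays per group. Other large rises were those of Tpsab1, a mast cell tryptase (3.60 ± 0.27), Procr, the receptor of protein C (3.10 ± 0.46), Rgs16, a regulator of G protein signalling (2.95 ± 0.43), Serpinb2, a plasminogen activator inhibitor (2.92 ± 0.47), and Vps37b of endosomal sorting (2.60 ± 0.48). Sprr2h (3.48 ± 0.74) and Gsta2 (3.21 ± 0.55) rose too. They and Tpsab1 belong to families of similar genes that a probe set may not tell apart. Large falls were those of the glutamate transporter Slc1a3 (-4.03 ± 0.49), the matrix proteoglycan Prelp (-3.81 ± 0.45), the RNA-binding protein Bicc1 (-3.46 ± 0.36), the growth arrest gene Gas1 (-3.41 ± 0.35), the receptor Ephb6 (-3.33 ± 0.49), Hacd4 (-3.28 ± 0.34), the Wnt modulator Sfrp2 (-3.18 ± 0.33) and the platelet-derived growth factor receptor Pdgfrb (-2.97 ± 0.19). Tcf19 (-2.75 ± 0.19), Ccn5 (-2.66 ± 0.47), Olfml3 (-2.65 ± 0.21), Mpnd (-2.61 ± 0.47) and Idh1, the cytosolic isocitrate dehydrogenase (-2.58 ± 0.22), also fell. For 5 of the 15 largest rises (Tpsab1, Procr, Serpinb2, Gsta2, Sprr2h) and 6 of the 15 largest falls (Bicc1, Prelp, Slc1a3, Ephb6, Ccn5, Mpnd), the lower group's mean log2 signal lay under that of the filter, so the size of the fold is imprecise.

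Genes of the unfolded protein response, which follows protein misfolding in the endoplasmic reticulum, rose almost throughout. Of 25 measured, 24 rose and 0 fell (24 and 0 adjusted over the list alone), and the exception was Ern1 (0.78 ± 0.45, and 0.45 to 1.07 on leaving out 1 array). The chaperone Hspa5 (BiP) rose by 1.39 ± 0.14, the secreted stress protein Manf by 1.94 ± 0.13, Sdf2l1 by 2.58 ± 0.19 and the degradation factor Herpud1 by 1.93 ± 0.13. Creld2, another secreted stress protein, rose 5.66-fold, from 2601 ± 207.2 to 14683 ± 369.6 (SD, n = 3). The list median was 1.22 (camera adjusted p = 8.54e-23, and adjusted p = 0.0179 with an estimated correlation). Targets of ATF4, the transcription factor of the integrated stress response, rose in 24 of 30 cases with 0 lower (24 and 0 adjusted over the list alone). Among them were Atf3 (2.51 ± 0.19), the pro-apoptotic factor Ddit3 (CHOP, 1.56 ± 0.14), which both lists hold, the amino acid transporter chain Slc3a2 (1.29 ± 0.15), the glutathione-degrading enzyme Chac1 (1.36 ± 0.17) and the pseudokinase Trib3 (1.35 ± 0.19). The ATF4 list had a median of 0.90 (adjusted p = 1.79e-16) and did not pass at an adjusted p = 0.0674 with an estimated correlation. Its median was 0.57 after hybridisation control scaling.

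Of 17 heat shock genes, 14 rose and 0 fell (14 and 0 adjusted over the list alone), led by Hspa1b (2.79 ± 0.17) and its near-identical copy Hspa1a (2.44 ± 0.30), which probes may not separate, then Hsph1 (1.62 ± 0.14), Dnajb1 (1.37 ± 0.14) and Hspb1 (1.11 ± 0.13). The median was 0.71 (adjusted p = 1.47e-11, and adjusted p = 0.0181 with an estimated correlation), and 0.38 after hybridisation control scaling. Of 20 oxidative stress genes, 10 rose and 1 fell (11 and 1 adjusted over the list alone). Besides Hmox1, the glutathione transferase Gsta4 rose by 2.19 ± 0.19, sulfiredoxin Srxn1 by 2.31 ± 0.20 and Gclm of glutathione synthesis by 1.80 ± 0.18, while glutathione peroxidase Gpx1 fell by 0.77 ± 0.17. This list had a median of 0.54 (adjusted p = 8.38e-08) and did not pass at an adjusted p = 0.0674 with an estimated correlation. Its median was 0.20 after hybridisation control scaling. Immediate-early genes and dual-specificity phosphatases, which follow growth factor and stress kinase signals, rose in 19 of 24 cases with 0 lower (21 and 0 adjusted over the list alone). Examples were Fos (2.20 ± 0.19), Ier3 (2.15 ± 0.15), Fosl1 (1.88 ± 0.16) and Myc (1.41 ± 0.14), with a median of 0.92 (adjusted p = 6.87e-16, and adjusted p = 0.0181 with an estimated correlation). The list median was 0.59 after hybridisation control scaling.

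Inflammatory genes moved both ways. Of 26 genes of the NF-kB list, 9 rose and 3 fell (9 and 3 adjusted over the list alone). Ptgs2, the inducible cyclooxygenase, rose 5.08-fold from 5289 ± 172.2 to 26964 ± 2921 (SD, n = 3), the cytokine Il6 by 1.76 ± 0.21, the chemokine Cxcl1 by 1.21 ± 0.18 and the growth factor Csf1 by 0.70 ± 0.13. The chemokine Ccl2 was at -0.039 ± 0.13 (adjusted p = 0.864). The chemokine Cxcl5 (-0.79 ± 0.20), the receptor Tlr2 (-0.76 ± 0.21) and the adhesion molecule Vcam1 (-0.51 ± 0.15) fell. Calls were lost for Csf1 after hybridisation control scaling (adjusted p = 0.129), for Cxcl5 without BSA 2, BSA 3 or palmitate 3, adjusted p up to 0.0816, for Tlr2 without BSA 2 or palmitate 2, adjusted p up to 0.107, and for Vcam1 without BSA 2, BSA 3, palmitate 2 or palmitate 3, adjusted p up to 0.134. The list median was 0.33 (adjusted p = 0.00684, and adjusted p = 0.341 with an estimated correlation) and -0.00032 after hybridisation control scaling, and leaving out 1 array moved it over 0.21 to 0.42. Interferon response and antigen presentation genes fell in 12 of 22 cases with 0 higher (16 and 0 adjusted over the list alone). The guanylate-binding protein gene Gbp2 fell by 2.25 ± 0.20, the immunoproteasome genes Psmb9 and Psmb8 had values of -2.10 ± 0.23 and -1.89 ± 0.18, and the antiviral gene Oasl2 fell by 1.10 ± 0.13. The median was -0.75 (adjusted p = 1.71e-07), and the list did not pass at an adjusted p = 0.0867 with an estimated correlation.

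**Figure D2:**
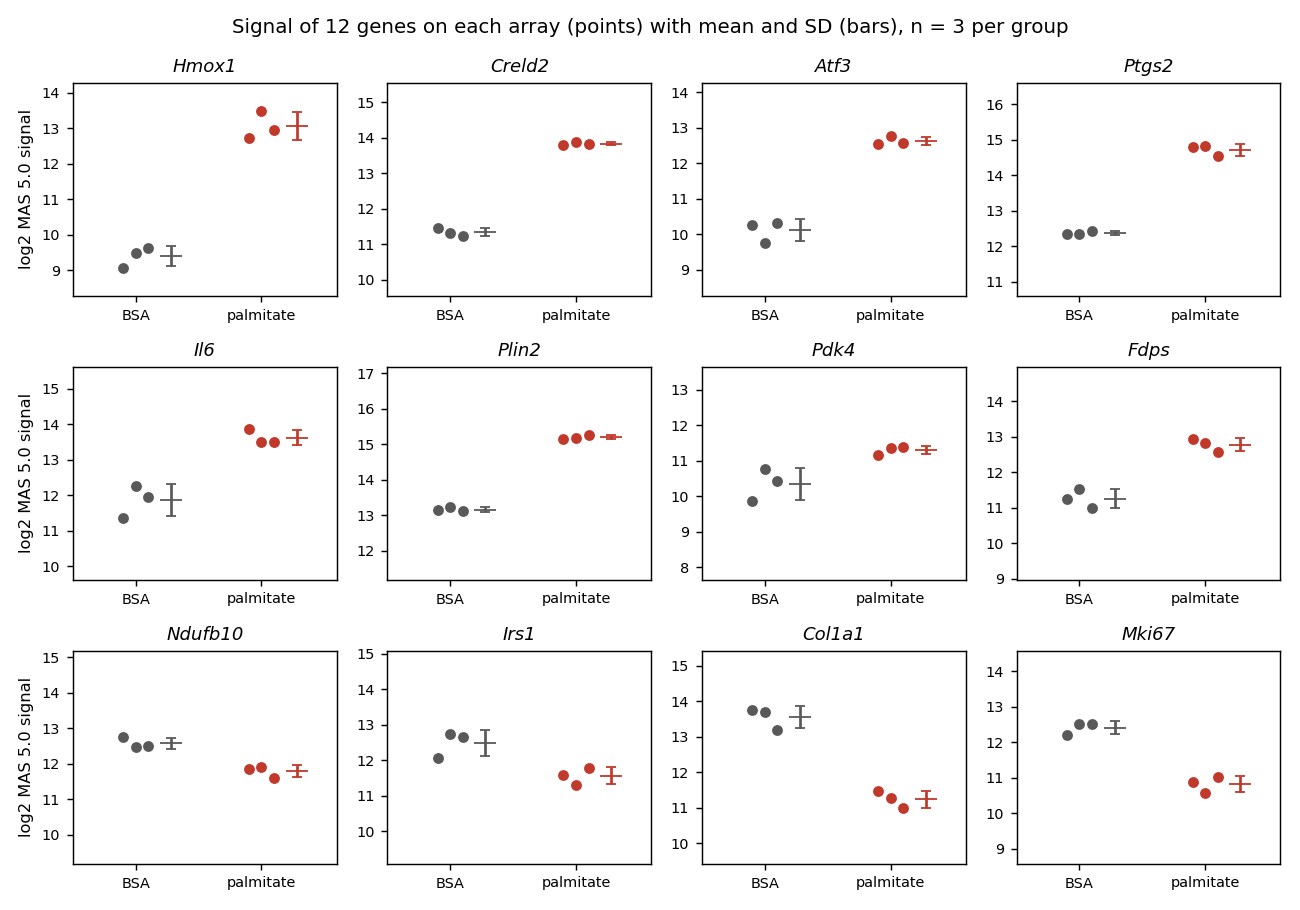
The log2 MAS 5.0 signal of 12 genes is plotted for each array (points) beside the mean and SD of its group (bars, n = 3), with BSA in grey and palmitate in red. In every panel the 3 palmitate arrays lie on the same side of the 3 BSA arrays.

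Of 15 targets of the PPAR nuclear receptors, 4 rose and 2 fell (4 and 3 adjusted over the list alone). Plin2 rose by 2.04 ± 0.12, from 9180.2 ± 389.6 to 37742 ± 1445 (SD, n = 3), the lipase inhibitor Angptl4 by 1.62 ± 0.15, the pyruvate dehydrogenase kinase Pdk4 by 0.94 ± 0.22 and catalase (Cat) by 0.70 ± 0.17. Lipoprotein lipase (Lpl, -1.16 ± 0.21) and the acyl-CoA dehydrogenase Acadm (-0.63 ± 0.15) fell, and the uncoupling protein gene Ucp3 was at 0.36 ± 0.46 (0.026 to 0.59 on leaving out 1 array). The list did not pass with camera (adjusted p = 0.443), with a median of -0.14 and a mean of 0.17. The sign of the median rests on the processing, since it was 0.42 without the filter, 0.025 with probe sets averaged, -0.47 after hybridisation control scaling and -0.16 to -0.021 on leaving out 1 array. Hybridisation control scaling ended the calls of Pdk4 (adjusted p = 0.0622) and Cat (0.225), and averaging its probe sets ended that of Lpl (-0.55, adjusted p = 0.173). The call of Cat also ended without palmitate 1, adjusted p = 0.0558, and that of Acadm without BSA 2, adjusted p = 0.0700.

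Enzymes of cholesterol synthesis rose in 9 of 18 cases with 0 lower (11 and 0 adjusted over the list alone). The sterol oxidase Msmo1 rose by 1.88 ± 0.17, farnesyl diphosphate synthase Fdps by 1.53 ± 0.18, lanosterol demethylase Cyp51 by 1.25 ± 0.19 and squalene epoxidase Sqle by 0.96 ± 0.16. The list median was 0.69 (adjusted p = 3.93e-06), and the list did not pass at an adjusted p = 0.0634 with an estimated correlation. Hybridisation control scaling moved this median to 0.35. Of 15 genes of fatty acid synthesis and desaturation, Acly (0.61 ± 0.16) and Fads3 (0.50 ± 0.16) rose and the elongase Elovl5 (-0.74 ± 0.19) fell (2 and 1 adjusted over the list alone). The desaturases Scd1 and Scd2 were at -0.13 ± 0.16 and 0.096 ± 0.14, and the list did not pass (adjusted p = 0.446). Averaged over its probe sets, Scd2 passed at 0.55 (adjusted p = 0.0275). The calls ended for Acly without palmitate 3, adjusted p = 0.0796, for Elovl5 without BSA 2, palmitate 1 or palmitate 2, adjusted p up to 0.0915, and for Fads3 without BSA 2, BSA 3, palmitate 2 or palmitate 3, adjusted p up to 0.155, and those of Acly and Fads3 also after hybridisation control scaling (adjusted p = 0.296 and 0.535).

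Of 14 triglyceride genes, the lipase Pnpla2 (0.63 ± 0.17) and the lipin Lpin3 (1.25 ± 0.37) rose, and the lipase inhibitor G0s2 (-1.34 ± 0.27), the acyltransferase Gpam (-0.76 ± 0.18) and the monoglyceride lipase Mgll (-1.22 ± 0.34) fell (2 and 3 adjusted over the list alone). Camera gave an adjusted p = 0.962 upward, with a median of 0.020 and a mean of -0.071. Of 14 ceramide and sphingolipid genes, 0 rose, and the glucosylceramide synthase Ugcg (-1.18 ± 0.18), the sphingomyelinase Smpd1 (-0.78 ± 0.20) and the phosphatase Sgpp1 (-0.83 ± 0.21) fell (2 higher and 3 lower adjusted over the list alone). Its adjusted p was 0.908 upward, with a median of 0.054 and a mean of -0.043. Calls were lost for Gpam without BSA 2, adjusted p = 0.0504, for Mgll without BSA 1 or palmitate 1, adjusted p up to 0.117, for Smpd1 without BSA 1 or palmitate 3, adjusted p up to 0.0520, and for Sgpp1 without BSA 2, BSA 3 or palmitate 3, adjusted p up to 0.0715. Ugcg kept its call with its probe sets averaged, but at -0.50 (adjusted p = 0.0495). Averaging ended those of Gpam (-0.38, adjusted p = 0.216), Mgll (-0.75, adjusted p = 0.132) and Sgpp1 (-0.48, adjusted p = 0.213). They also ended for Pnpla2 without BSA 2, BSA 3, palmitate 1 or palmitate 3, adjusted p up to 0.0868, and for Lpin3 without BSA 2, BSA 3, palmitate 2 or palmitate 3, adjusted p up to 0.117, and for both after hybridisation control scaling (adjusted p = 0.361 and 0.0902).

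Of 73 oxidative phosphorylation genes, 14 fell and 0 rose (27 and 0 adjusted over the list alone), with a median of -0.33 (-0.66 after hybridisation control scaling). Complex I held 10 of the 14, among 33 measured subunits with a median of -0.37, including Ndufb10 (-0.78 ± 0.16), Ndufa6 (-0.65 ± 0.14) and Ndufb7 (-0.65 ± 0.14). The other 4 were Atp5k (-0.89 ± 0.19) and Atp5j2 (-0.53 ± 0.14) of ATP synthase, Uqcrh of complex III (-0.57 ± 0.17) and Sdhd of complex II (-0.47 ± 0.14). Of 11 subunits of complex IV, 0 passed, at a median of -0.25. The list passed with camera (adjusted p = 3.71e-06) and with fry (adjusted p = 0.0214). It did not pass at an adjusted p = 0.341 with an estimated correlation. That correlation was 0.195, so its genes varied together between arrays, but the test also has fewer degrees of freedom. The calls ended for Atp5j2 without BSA 2, palmitate 1 or palmitate 3, adjusted p up to 0.0913, for Uqcrh without any array but palmitate 3, adjusted p up to 0.115, and for Sdhd without any single array, adjusted p up to 0.138.

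Of 19 fatty acid oxidation genes, 5 fell and 0 rose (7 and 0 adjusted over the list alone). The falls were those of the enzymes Acadm (-0.63 ± 0.15), Decr1 (-0.75 ± 0.18), Echs1 (-0.68 ± 0.17), Acaa2 (-0.64 ± 0.18) and Eci2 (-0.52 ± 0.17), while Cpt1a, which admits fatty acids to mitochondria, was at -0.49 ± 0.18 (adjusted p = 0.0766, 0.0141 after hybridisation control scaling and 0.0490 with probe sets averaged). The list median was -0.35 (adjusted p = 0.00684, and adjusted p = 0.283 with an estimated correlation). Calls were lost for Acadm without BSA 2, adjusted p = 0.0700, for Decr1 without BSA 2, adjusted p = 0.0698, for Acaa2 without any array but BSA 3, adjusted p up to 0.0915, and for Eci2 without any array but BSA 1, adjusted p up to 0.178, and that of Acaa2 also with its probe sets averaged (-0.48, adjusted p = 0.0697).

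Other mitochondrial lists did not pass. Of 17 genes of the citric acid cycle and pyruvate dehydrogenase, Idh2 fell by 1.10 ± 0.23 and 0 rose (1 lower and 0 higher adjusted over the list alone), citrate synthase Cs was at -0.23 ± 0.13 (-0.57, adjusted p = 0.0197, after hybridisation control scaling), and the list median was -0.23 (adjusted p = 0.142, 0.0482 after hybridisation control scaling and 0.0350 without the filter). Of 74 mitochondrial ribosomal proteins, 2 rose, Mrps18b (0.92 ± 0.21) and Mrps6 (0.73 ± 0.17), and 6 fell, among them Mrpl18 (-1.04 ± 0.23), with 2 and 4 adjusted over the list alone (list adjusted p = 0.586). Of 15 regulators of mitochondrial transcription, Gabpb1 rose by 0.71 ± 0.18 and 0 fell (1 and 0 adjusted over the list alone, list adjusted p = 0.167). The coactivator Ppargc1b was at -0.57 ± 0.20 (adjusted p = 0.0679) but passed after hybridisation control scaling (-0.91, adjusted p = 0.00928) and in the fit on averaged probe sets (adjusted p = 0.0436). The nuclear receptor gene Esrra was at -0.11 ± 0.21, and the probe sets of Ppargc1a and of the glucose transporter Slc2a4 lay below the signal filter. The calls of Mrps18b, Mrps6 and Gabpb1 ended after hybridisation control scaling (adjusted p = 0.0803, 0.165 and 0.257), and that of Gabpb1 without BSA 2, palmitate 2 or palmitate 3, adjusted p up to 0.0700.

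Called genes of glucose use and of insulin signalling included both rises and falls. Of 17 glycolysis genes, hexokinase Hk2 (1.09 ± 0.17), the glucose transporter Slc2a1 (0.88 ± 0.14) and the liver phosphofructokinase Pfkl (0.67 ± 0.21) rose, and the muscle isoforms Pgam2 (-2.13 ± 0.42) and Pfkm (-0.74 ± 0.18) fell (3 and 3 adjusted over the list alone). The list did not pass (adjusted p = 0.586 upward), with a median of 0.097 (-0.24 after hybridisation control scaling, and 0.037 to 0.14 on leaving out 1 array) and a mean of -0.052. Of 13 insulin signalling genes, the receptor substrate Irs1 (-0.92 ± 0.20), the transcription factor Foxo1 (-0.70 ± 0.19) and the kinase subunit Pik3r1 (-0.94 ± 0.28) fell and the translation repressor Eif4ebp1 (0.55 ± 0.12) rose (3 lower and 1 higher adjusted over the list alone). The insulin signalling list did not pass with camera (adjusted p = 0.586) but did with fry, downward (adjusted p = 0.00552). Hybridisation control scaling ended the calls of Pfkl (adjusted p = 0.324) and Eif4ebp1 (0.384). The calls also ended for Pfkl without any array but BSA 1, adjusted p up to 0.160, for Foxo1 without BSA 1, BSA 2, palmitate 1 or palmitate 2, adjusted p up to 0.0884, and for Pik3r1 without BSA 2, BSA 3, palmitate 2 or palmitate 3, adjusted p up to 0.135.

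Of 28 matrix and fibroblast genes, 22 fell and 1 rose (22 and 1 adjusted over the list alone). The collagen genes Col6a1 (-2.56 ± 0.15), Col1a1 (-2.31 ± 0.19), Col3a1 (-1.89 ± 0.15) and Col1a2 (-1.63 ± 0.12) were among the falls, and the matricellular gene Ccn1 rose by 1.14 ± 0.16. The median was -0.91 (adjusted p = 1.43e-13), and the list did not pass at an adjusted p = 0.0674 with an estimated correlation. Of 32 cell cycle genes, which mark dividing and so unfused cells, 22 fell and 0 rose (25 and 0 adjusted over the list alone). Thymidine kinase Tk1 (-2.60 ± 0.20), the proliferation marker Mki67 (-1.59 ± 0.17) and the replication genes Mcm6 (-1.31 ± 0.15) and Mcm7 (-1.16 ± 0.14) fell. The median was -0.99 (adjusted p = 1.47e-11), and the list did not pass at an adjusted p = 0.0634 with an estimated correlation. Both lists hold genes of unfused cells, and on the same arrays the sarcomere list had a median of -0.15. Of 5 macrophage and leukocyte genes, 0 rose and 0 fell (0 adjusted over the list alone, list adjusted p = 0.731). The osteoblast and adipocyte lists had 2 and 4 measured genes, too few to test, of which 0 and 1 fell (0 and 3 adjusted over the list alone), the latter being Lpl.

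Of 41 sarcomere genes, tropomyosin Tpm2 (-0.76 ± 0.15) and the calcium pump Atp2a1 (-0.60 ± 0.18) fell and 0 rose (1 lower and 0 higher adjusted over the list alone), the myosin Myh1 was at -0.14 ± 0.15 (-0.47, adjusted p = 0.0478, after hybridisation control scaling, and -0.22 to -0.013 on leaving out 1 array) and creatine kinase Ckm at -0.33 ± 0.29. The list did not pass (adjusted p = 0.304), but did without BSA replicate 3 (0.0116, median -0.30), and its median was 0.038 without BSA replicate 1. Of 14 myogenic regulators, Myod1 (-1.33 ± 0.16), Id3 (-0.82 ± 0.22) and Id2 (-0.79 ± 0.25) fell and 0 rose (4 lower and 0 higher adjusted over the list alone), and Myog was at -0.019 ± 0.16. Myod1 drives myogenesis and the Id proteins oppose it. The list median was -0.31 (adjusted p = 0.0460, and adjusted p = 0.296 with an estimated correlation), and its call ended without BSA 1, palmitate 1, palmitate 2 or palmitate 3, adjusted p up to 0.128. Averaging over probe sets ended the calls of Tpm2 (-0.40, adjusted p = 0.0941) and Id2 (-0.22, adjusted p = 0.700). The calls ended for Atp2a1 without any array but BSA 3, adjusted p up to 0.106, for Id3 without BSA 1, BSA 3, palmitate 1 or palmitate 3, adjusted p up to 0.0866, and for Id2 without BSA 2, BSA 3, palmitate 2 or palmitate 3, adjusted p up to 0.171.

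Proteolysis genes moved both ways. Of 22 atrophy and autophagy genes, the autophagy receptor Sqstm1 rose by 1.42 ± 0.13, and Foxo1 (-0.70 ± 0.19) and the ubiquitin ligase Fbxo32 (-0.71 ± 0.21) fell (1 and 2 adjusted over the list alone, list adjusted p = 0.962). Of 37 proteasome subunits, Psmd8 (0.74 ± 0.15), Psmb2 (0.54 ± 0.13), Psmd11 (0.47 ± 0.13) and Psmd14 (0.50 ± 0.15) rose, and the interferon-inducible Psmb8, Psmb9 and Psmb10 (-0.98 ± 0.29) fell (5 and 3 adjusted over the list alone). The proteasome median was 0.17 (adjusted p = 0.0462, and adjusted p = 0.519 with an estimated correlation) but -0.16 after hybridisation control scaling, and the list's call ended without any array but BSA 1, adjusted p up to 0.189. Hybridisation control scaling ended the calls of Psmd8 (adjusted p = 0.135), Psmb2 (0.446), Psmd11 (0.564) and Psmd14 (0.478). The calls also ended for Foxo1 without BSA 1, BSA 2, palmitate 1 or palmitate 2, adjusted p up to 0.0884, for Fbxo32 without BSA 2, BSA 3, palmitate 1 or palmitate 2, adjusted p up to 0.133, and for Psmb2 without BSA 2 or BSA 3, adjusted p up to 0.0735. They ended for Psmd11 without BSA 2, BSA 3, palmitate 1 or palmitate 3, adjusted p up to 0.0917, for Psmd14 without any array but palmitate 2, adjusted p up to 0.135, and for Psmb10 without BSA 1, BSA 2, palmitate 1 or palmitate 3, adjusted p up to 0.115. Averaging over probe sets ended those of Fbxo32 (-0.47, adjusted p = 0.151) and Psmd11 (0.24, adjusted p = 0.230).

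Of 42 cytosolic ribosomal proteins, Rpl12 rose by 0.90 ± 0.21 and 0 fell (0 and 0 adjusted over the list alone). The list did not pass (adjusted p = 0.586 upward), with a median of -0.0062 and a mean of 0.038. Of 25 apoptosis and p53 genes, 6 rose, including the p53 inhibitor Mdm2 (1.11 ± 0.16), Gadd45b (0.94 ± 0.14) and the pro-apoptotic Bbc3 (0.99 ± 0.20), and 4 fell (6 and 4 adjusted over the list alone, list adjusted p = 0.219). The falls were those of Casp12 (-1.35 ± 0.23), Casp6 (-0.99 ± 0.21), the caspase inhibitor Xiap (-0.62 ± 0.19) and Sesn1 (-0.62 ± 0.20). Hybridisation control scaling ended the calls of Rpl12 (adjusted p = 0.144) and Bbc3 (0.0740). Calls were lost for Xiap without BSA 2, BSA 3, palmitate 2 or palmitate 3, adjusted p up to 0.145, and for Sesn1 without any array but palmitate 2, adjusted p up to 0.173. With probe sets averaged the calls of both ended too, Xiap at -0.023, adjusted p = 0.959, and Sesn1 at -0.45, adjusted p = 0.121.

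**Figure D3:**
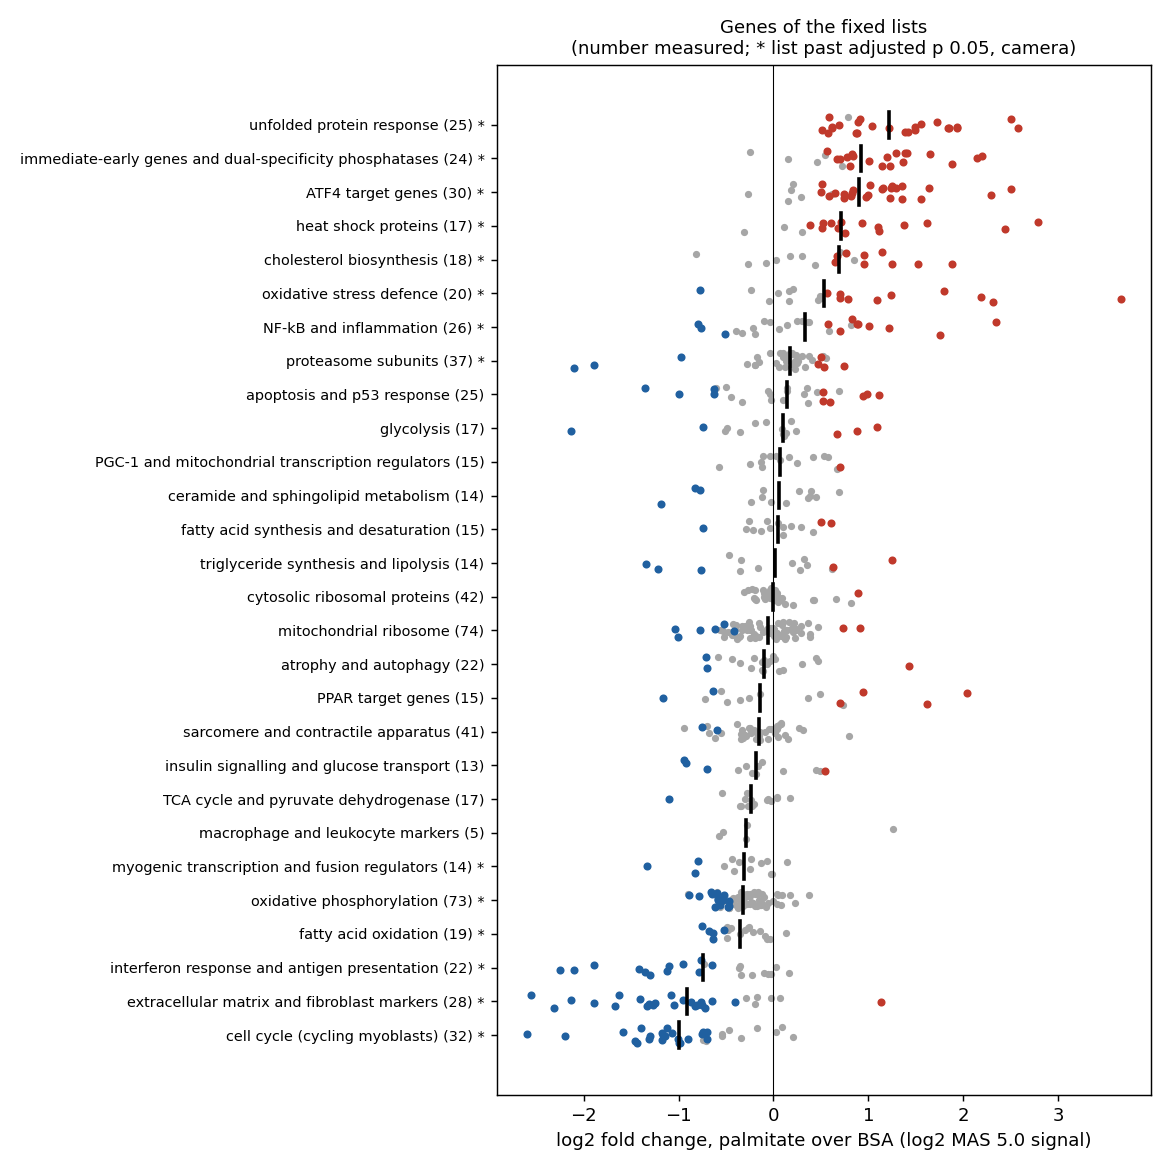
Each point is a gene of a fixed list, placed by its log2 fold change (palmitate over BSA), with lists ordered by their median (black bar), red points higher, blue points lower and grey points not past an adjusted p of 0.05. Medians run from -0.99 for the cell cycle list to 1.22 for the unfolded protein response list, and after hybridisation control scaling the proteasome median turns to -0.16.

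Of the 28 lists tested, 14 passed with camera's preset correlation, 8 higher and 6 lower. With an estimated correlation 3 passed, those of the unfolded protein response, heat shock proteins and immediate-early genes. Fry gave 17, of which 13 were among the 14, and the other 4 were the citric acid cycle, PPAR, insulin signalling and macrophage lists (adjusted p = 0.00177, 0.00432, 0.00552 and 0.0179). Among these 4, fry's direction was up for the PPAR list, against its median of -0.14, and down for the others. The number of lists alone separates the groups poorly, since the 9 other splits of the 6 arrays into 3 and 3, which keep 33.3% of the group difference, gave 10 to 13 lists each.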

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

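Both tests in this part were chosen only after the data were seen. The 9 hybridisation control probe sets, which measure RNA added to the samples and not RNA of the cells, were brighter on the palmitate arrays by 0.33 in mean log2 signal. All 9 had the higher mean there, and for 5 of them each palmitate array lay above each BSA array (exact permutation p = 0.1 for the mean, the smallest possible with 3 arrays per group). Of the 9051 probe sets below the signal filter, which the comparisons of the report leave out, 102 passed when limma was fitted without the filter, 45 higher and 57 lower with palmitate. Among them, named after their values were seen, were another probe set of Pdgfrb, with a mean signal of 1437 with BSA and 50 with palmitate (limma adjusted p = 1.25e-04), Nrep (944.9 and 20.2), Angpt1 (687.6 and 35.0) and the immediate-early gene Egr4 (63.1 and 730.3).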

How the results depend on the processing

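Hybridisation control scaling and the fit without both arrays at the far end of component 2 were chosen only after the data were seen. Across the other scalings, filters and variance models the count of probe sets ran from 2039 without the intensity trend to 2676 with the log offset. Hybridisation control scaling moved it to 404 higher and 3169 lower, by its own construction a shift of every probe set down by the brightness of those controls. Leaving out 1 array gave 1579 to 2315 probe sets, 746 to 1085 higher and 833 to 1282 lower, each lowest without BSA replicate 2. All of these fits lacked 1 array, so the number of samples does not set that fit apart, and the cause was not tested. The replicate numbers share no pairing beyond the number: deviations of same-numbered arrays correlated at -0.23, -0.13 and 0.0091 and every array correlated more with an array of another number, and the replicate block gave 1973 probe sets, 855 higher and 1118 lower. With an estimated correlation 3 lists passed in place of 14, and the oxidative phosphorylation list, still at a median of -0.33, had an adjusted p = 0.341, the highest of its alternatives, the lowest being 5.20e-09. The myogenic list kept its call in 9 of 20 alternatives and the proteasome list in 5 of 20. Of 149 called genes among 161 followed through the alternatives, 99 kept their call in all that could be run, 16 lost it in 1, 8 in 2 to 4 and 26 in 5 or more, and 0 reversed. Reversals of a test's direction or a gene's sign were seen only among lists and genes that had not passed, and the cause was not tested. Where the test of a list turned, its medians were as follows. The triglyceride median was 0.20 without the filter, 0.020 with the replicate block, 0.020 with fry, and -0.038 to 0.17 on leaving out 1 array. The ceramide median was -0.28 with hybridisation control scaling, -0.027 without the filter, -0.068 with the stricter filter, 0.054 with fry, and 0.015 to 0.14 on leaving out 1 array. The sarcomere median was 0.040 without both component 2 arrays and -0.30 to 0.038 on leaving out 1. The macrophage median was -0.63 with hybridisation control scaling and 0.64 without the filter, and that of cytosolic ribosomal proteins -0.34 with hybridisation control scaling. The atrophy median was -0.068 with median scaling, -0.064 with 75th percentile scaling, -0.095 with the replicate block, -0.10 with probe sets averaged, and -0.15 to -0.015 on leaving out 1 array. Leaving out 1 array moved Ccl2 over -0.11 to 0.010, Esrra over -0.23 to 0.033, Scd1 over -0.22 to 0.022, Scd2 over -0.0054 to 0.18, Ckm over -0.52 to 0.014, Myog over -0.18 to 0.16 and Psmb10 over -1.24 to -0.61. It moved the proteasome median over 0.11 to 0.19 and that of cytosolic ribosomal proteins over -0.064 to 0.038. Scd1 was at 0.19 with probe sets averaged, Scd2 at -0.24 with hybridisation control scaling and, past the threshold, at 0.55 with probe sets averaged, and Myog at 0.0073 and 0.011 with median and 75th percentile scaling. Without palmitate replicate 2, whose 3' to 5' control ratios were lowest, 2224 probe sets passed, 942 higher and 1282 lower. Without both component 2 arrays Scd2 was at -0.020, Myh1 at 0.096 and Myog at 0.14. Among genes named in the report, calls that held but at a value changed more than 1.5-fold included Gas1 (-2.23), Atp5k (-0.59), Ugcg (-0.50) and Eif4ebp1 (0.92) with probe sets averaged, and among the rises Sqle (0.63), Slc2a1 (0.55) and Gadd45b (0.61) after hybridisation control scaling, which likewise enlarged several smaller falls. Without a call, Cs was at -0.040 and Myh1 at -0.067 with probe sets averaged, Ucp3 at 0.026 after hybridisation control scaling, and Ern1 at 0.28 without both component 2 arrays. Signal over background is not known here, so folds of genes whose lower group is dim stay imprecise.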

Other observations

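The tests chosen only after the result was seen were the screen of symbol families, the splits of the arrays, hybridisation control scaling, the highest medians across scalings, the comparison of medians for unfused cells, and the random lists for small nucleolar RNA host genes. The genes named here lie outside the rule for named genes. A screen took 114 families of at least 8 measured genes that share the letters of their symbol. With camera's preset correlation 10 passed, and with an estimated correlation 0 did (lowest adjusted p = 0.478). The latter test has fewer degrees of freedom (for the Mcm genes the camera p went from 5.29e-06 to 0.00922). Adjusted over 114 families, it could hardly pass a small family, so the count of 0 decides little. Of 8 Nop genes of nucleolar proteins, 5 rose and 0 fell, among them Nop58 (1.32 ± 0.23), Nop14 (1.19 ± 0.17) and Nop16 (1.12 ± 0.18), with a median of 0.72 (adjusted p = 0.00399) and 0.38 after hybridisation control scaling. Of 8 Rrp genes of ribosomal RNA processing, 4 rose and 0 fell, including Rrp9 (1.57 ± 0.24) and Rrp12 (0.99 ± 0.23), with a median of 0.66 (adjusted p = 0.00399) and 0.32 after hybridisation control scaling. Of 26 Ddx RNA helicase genes, 5 rose, including Ddx18 (0.86 ± 0.18), and Ddx60 fell by 0.83 ± 0.18, and their median of 0.23 (adjusted p = 0.0279) turned to -0.10 after hybridisation control scaling. That scaling also ended the calls of Rrp12 (adjusted p = 0.0738) and Ddx18 (0.0996).

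In the same screen, of 12 Ift genes of intraflagellar transport, which builds the primary cilium, 5 fell and 0 rose, including Ift46 (-0.99 ± 0.22), Ift140 (-1.01 ± 0.29) and Ift80 (-1.26 ± 0.36), with a median of -0.67 (adjusted p = 0.0292, and adjusted p = 0.507 with an estimated correlation). The calls ended for Ift140 without BSA 1, BSA 2 or palmitate 1, adjusted p up to 0.107, and for Ift80 without BSA 2, BSA 3, palmitate 2 or palmitate 3, adjusted p up to 0.126, and that of Ift80 also with its probe sets averaged (-0.75, adjusted p = 0.0792). Of 9 interferon-inducible Ifi genes, 7 fell and 0 rose, including Ifi44l (-1.98 ± 0.24) and Ifi47 (-1.70 ± 0.17), with a median of -0.65 (adjusted p = 0.00103, and adjusted p = 0.525 with an estimated correlation). Both medians stayed below 0 under the 4 other scalings.

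The oxidative phosphorylation list had a median of -0.33, with 14 of 73 genes past the threshold as lower. A signal-dependent bias between arrays would shift random lists of like signal as far, but the list lay at percentile 0 of 10000 random lists matched on mean signal, whose central 95% ran from -0.11 to 0.11. Array scaling as the whole cause was not decided by 4 other scalings, where the highest list median was -0.29. Median, 75th percentile and quantile scaling left the median of all genes at -0.031 to -0.020, against -0.051 as deposited. Hybridisation control scaling lowered it to -0.38, and the list to -0.66. Shifts of that size and direction could not bring the list to 0. Only 1 of the 10 splits of the arrays, the real one, gave a median as far from 0 (0.33 against 0.21 for the highest other), and 10 splits are too few for a share under 0.05. The other splits keep only part of the group difference, which by itself makes their medians smaller. With camera's preset correlation the list also passed in 6 of the 9 other splits, and 2 gave a smaller p than the real one. Random lists treat genes as independent, so a variation shared by these genes between arrays (estimated correlation 0.195) stays open, beside an effect of palmitate, which may also account for the fall. Camera with that correlation gave an adjusted p = 0.341, to which its fewer degrees of freedom also contribute.

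The falls of the extracellular matrix and cell cycle lists may reflect a smaller share of unfused cells, whose genes both lists hold. If both lists marked only unfused cells, which was not tested, a smaller share would lower both alike and raise sarcomere genes. The medians differed by 0.084, against a bootstrap standard error of 0.20 from resampling the genes of each list. That error takes genes as independent and leaves out the spread between arrays, so it does not test whether the falls are alike. The sarcomere median was -0.15, and its camera adjusted p = 0.304 rests on a preset correlation far under its estimated 0.558. A smaller share and a lower expression within cells under palmitate therefore cannot be told apart on these arrays of mixed cells. Array scaling as the whole cause was not decided by 4 other scalings, where the highest median for either list was -0.88. Median, 75th percentile and quantile scaling moved all genes little. Hybridisation control scaling moved them down, the matrix median to -1.24 and the cell cycle median to -1.33. None of these could bring the lists near 0.

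All 5 measured noncoding host genes of small nucleolar RNAs rose, Snhg1 (1.32 ± 0.14), Snhg5 (1.07 ± 0.21), Gas5 (1.06 ± 0.12), Snhg6 (0.86 ± 0.18) and Snhg8 (0.67 ± 0.15). Their median lay at percentile 99.97 of 10000 random lists matched on mean signal, but the genes were taken up because they had risen, so that percentile restates their rise and decides nothing about a rise of the class. After hybridisation control scaling the median was 0.72, and the calls of Snhg6 and Snhg8 ended (adjusted p = 0.0831 and 0.223). Cytosolic ribosomal proteins had a median of -0.0062, and whether synthesis or decay of the host transcripts differed was not tested.

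Of the 10 splits of the 6 arrays, 1, the real one, gave as many as 2609 probe sets, with 0 as the highest other. Likewise 1 of 10 gave as many as 14 lists, with 13 as the highest other, and 10 splits are too few for a share under 0.05. Each other split also mixes palmitate and BSA arrays, so any group difference widens the spread within its groups and lowers its count of probe sets. The count of 0 there therefore cannot decide about chance.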
